A study of Mus musculus with 6 samples.

How the data were processed

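Gene expression was measured by RNA sequencing of 6 mouse lymph node samples, 3 labelled Control and 3 labelled Naringin. Naringin is the flavanone glycoside that gives grapefruit its bitter taste. Per the labels, it was given daily in the food at 200 mg/kg, and the inguinal lymph nodes, which lie in the fat under the skin of the groin, were then taken. Per the labels' protocols, RNA was purified with an RNeasy column kit and libraries were made from 1 µg of total RNA with the NEBNext Ultra kit. The duration of feeding, the strain, age and sex of the mice and the food of the Control group are not given in the sources used here. Nothing in the labels says that the 3 samples of a group came from separate animals. The p-values of single genes therefore measure only the spread among these samples, which may be partly technical.

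The submitters' processing notes name Trimmomatic 0.39, STAR 2.7.9a, featureCounts from Subread 1.6.0 and edgeR 3.40.0, with the mouse genome build mm39. The gene annotation and the strand setting are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. The deposited table holds 50559 genes as CPM: the authors divided each gene's reads by the library total and multiplied by 1000000, with no further scaling factor, since each column summed to that number. A CPM value is a share of a library's reads, so a large change in some genes moves the others. Every value was a whole multiple of the worth of 1 read, and 100% of the values above 0 came out whole within 0.01 of a read. The recovered totals were 13074180, 13834251 and 14963386 reads in Control 1, 2 and 3, and 14924805, 14976422 and 14276848 reads in Naringin 1, 2 and 3. A single read was therefore worth 0.0668 to 0.0765 CPM. No 2 libraries were alike within sampling noise: the chi-square per degree of freedom between libraries, over genes with at least 20 reads in the pair, ran from 7.68 to 61.6.

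Values were analysed as log2(CPM + 1), so every fold change is on that scale and understates the change of low genes. Genes with a mean of at least 1 CPM over the 6 libraries were tested, which left 14873 of the 28727 genes with a read. The test was limma 3.58.1 in R 4.3.3 with a mean-variance trend and robust variance moderation, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors (SE) are limma's moderated ones, and SDs are over the 3 libraries of a group. Before the data were examined, 45 gene lists were fixed for the cell types of a lymph node and its surrounding tissue, for immune signalling, and for metabolism and stress. The 43 lists with at least 5 tested members were compared with all other genes by limma's camera with a preset correlation of 0.01, 2-sided and adjusted over the lists. With the correlation preset, a camera p-value rests on the spread between genes. It does not measure how far a list's difference varies between samples. The lists for brown adipocytes and for keratin and mammary epithelium had 2 tested members each and were left out.

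The genes named in the text follow a rule fixed at the same time. Because fewer than 5 genes passed in either direction, the 10 genes with the smallest p in each direction are named, leaving out predicted genes with Gm or Rik names, pseudogenes and antigen receptor segments. The rule adds the 3 members with the smallest p in the direction of each list past its threshold, and the 2 with the smallest p of each other list described. Adipoq, Krt14, Acta1 and Cd3e were named as a tissue check. Some genes that the rule takes are not reported here. Cxcr4, Cd209b, Cd209c, Cd209d, Cd209e, Ighm, Trac, Igk and Tcrb were chosen after their values were seen. No coordinates are given, since the annotation used here is of an older build. GENCODE M21 gave an exon length, which is the total over all exons of a gene, and GC content for 93.8% of the tested genes.

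The alternatives fixed before the data were examined were other pseudocounts, filters and scalings, a replicate block, limma without trend, sample weights, an adipocyte covariate, leaving out each library, and other tests for the lists. Count tests on the recovered reads were run with edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 (Wald test). They called 0 and 3 genes. A gene-length correction, alone or without Control 3, and a macrophage covariate were chosen after seeing the data. The same steps were tested on simulated reads for 14873 genes drawn with the real means, depths and spread. With 200 genes changed, limma recovered 51% of the 2-fold and 94% of the 4-fold changes, with 12 calls among 14648 unchanged genes. For this comparison edgeR recovered 48% and 94%, with 10 such calls, and DESeq2 63% and 93%, with 40. A simulated list shifted by 1.5-fold was called by camera, and 0 other lists were. The simulated genes varied independently of each other. The simulation therefore cannot show how often camera calls lists in error where genes vary together. Nor does it show what share of changes would be recovered in that case, or with fewer changed genes.

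Of 542 antigen receptor constant and variable genes in the table, 534 were listed at 0 in every library, among them Ighm and Trac and 7 of the 8 heavy chain constant genes. Reads of the loci were instead listed under names such as Igk and Tcrb. Shares of antibody classes, planned before the data were examined, were therefore not computed.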

Results

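The transcriptome of inguinal lymph nodes was compared between 3 mouse samples labelled Control and 3 that received naringin, a citrus flavonoid, at 200 mg/kg per day in the food. The comparison asks which genes and cell types of the node differ with naringin in the diet. The libraries held 13074180 to 14976422 reads assigned to genes. The T cell receptor component Cd3e, a marker of the node itself, lay between 156 and 248 CPM. Of the markers of surrounding tissue, the fat hormone Adipoq ranged from 0.770 CPM in Naringin 3 to 4.05 CPM in Control 1, the skin keratin Krt14 had at most 4 reads, and the muscle actin Acta1 at most 6 reads in a library. Fat was uneven between libraries: the adipocyte gene Cfd lay at 24.6 CPM in Control 1 and 1.75 CPM in Naringin 3, and Car3 at 21.5 and 2.31 CPM.

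With naringin, genes of the type I interferon response were higher as a group, by a median log2 fold of 0.61 over 25 members, and T cell genes were lower, by a median of -0.22 over 21 members. B cell, fatty acid oxidation, glucocorticoid and haemoglobin genes were also higher as groups, and dendritic cell and adipocyte genes lower. Among single genes, the lectins Cd209g and Cd209f had the largest falls in mean relative to their error. The hormone gene Fgf23 had the largest gain. But no single gene passed the adjusted threshold in limma with all 6 libraries and no sample weights. The calls for groups rest on a preset correlation between genes and ended with an estimated one. Of the 10 ways to split the libraries into equal groups, 9 passed at least as many lists, the real split included. The B cell, dendritic cell and adipocyte calls were also lost when certain single libraries were left out.

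Of 14873 genes tested with limma, 0 were higher and 0 were lower at an adjusted p under 0.05, and the smallest adjusted p was 0.9996. At an unadjusted p under 0.05 there were 213 genes, 145 higher and 68 lower with naringin, where chance gives about 744. The excess of higher genes was not stable: upper-quartile scaling gave 115 higher and 118 lower, median-of-ratios 133 and 93, and quantile normalization 128 and 102. The split was 398 higher and 993 lower without Control 3, 400 and 113 without Naringin 3, 71 and 61 without Naringin 1, and 46 and 26 without Naringin 2. All 3 naringin values lay above all control values in 499 genes and below them in 341, together 5.65% of the genes, against 10% by chance. The edgeR test on recovered reads called 0 genes, with 233 at an unadjusted p under 0.05, and DESeq2 called 3: Cd209g, Cd209f and Fgf23. The genes described next are therefore those with the smallest p, and none of them passed in limma without sample weights. Choosing genes by p favours those whose groups do not overlap, so a lack of overlap is no added evidence for them. Weighting the libraries by their estimated quality gave 1367 calls, 560 higher and 807 lower, but that estimate did not converge and gave Naringin 2 a weight of 8.34 and Control 3 a weight of 0.122.

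The genes with lower means were led by 2 C-type lectins of the Cd209 family, mouse relatives of the dendritic cell receptor DC-SIGN. Cd209g averaged 8.93 ± 2.48 CPM in Control and 1.87 ± 0.918 CPM with naringin (SD, n = 3 each), a log2 fold of -1.82 ± 0.29 (SE). Cd209f averaged 30.2 ± 7.23 CPM and 12.3 ± 4.51 CPM, a log2 fold of -1.26 ± 0.27 (SE). In both, every naringin value lay below every control value. By DESeq2, Cd209g had a log2 fold of -2.28 with an adjusted p of 0.00015. Cd209f had -1.31 with a DESeq2 adjusted p of 0.0489, close to the threshold. In the simulated reads DESeq2 made 40 calls among unchanged genes, against 12 by limma. The family was looked at further after these values were seen. Cd209e, Cd209d, Cd209a and Cd209c had log2 folds of -0.88, -0.71, -0.55 and -0.35, with Cd209e at -0.52 without Control 2, Cd209d at -1.10 without Control 1 and Cd209c at -0.54 without Naringin 1 and -0.19 without Naringin 2. The 6 genes other than Cd209b summed to 112 ± 14.3 CPM in Control and 57.2 ± 9.95 CPM with naringin. Cd209b, the most abundant member and a receptor of sinus and marginal zone macrophages, stood at 570 ± 195 and 668 ± 389 CPM, and its log2 fold of 0.08 turned to -0.22 without Control 1, -0.34 without Naringin 1 and -0.05 without Naringin 2. These genes are close paralogs, as are Klra4 and Klra8, Hba-a1 and Hba-a2, and Oas2 and its relatives; how shared reads were counted is not given in the sources used here, so the share of each gene is uncertain.

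The other genes at the low end were Mira, Zfp683 (Hobit, a transcription factor of tissue-resident lymphocytes), Mid1, Bpifb3, Cc2d1a, Sult5a1, Cd5 and LOC115486406. Their log2 folds ran from -0.99 for Bpifb3 to -0.38 for Cc2d1a, and that of Bpifb3 was -0.58 without Control 2. Cd5, a receptor that dampens T cell receptor signalling, averaged 167 ± 3.69 CPM in Control and 128 ± 16.7 CPM with naringin. All 8 were lower in every naringin library than in every control library.

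Among the genes with higher means, Fgf23, a hormone that lowers blood phosphate and is made mainly in bone, came first. It had 6 reads over the 3 control libraries (3, 0 and 3) and 111 over the 3 naringin libraries (56, 27 and 28). The ratio per read sequenced was 17.5, with an exact binomial 95% interval of 7.81 to 48.8 that covers counting error only. On the log2 scale it differed by 1.58 ± 0.25 (SE, n = 3 each). The secreted proteoglycan-cleaving proteases Adamts1 and Adamts4 had log2 folds of 1.15 ± 0.26 and 0.99 ± 0.24, with Adamts1 at 4.70 ± 0.532 CPM in Control and 12.1 ± 4.37 CPM with naringin. Glycam1, a mucin-like ligand for L-selectin made by high endothelial venules, averaged 228 ± 59.6 and 404 ± 67.6 CPM. The follicular chemokine Cxcl13, which draws in B cells, averaged 186 ± 45.5 and 333 ± 68.2 CPM. Ddit4, a stress- and glucocorticoid-induced inhibitor of mTOR signalling, averaged 116 ± 28.4 and 197 ± 27.9 CPM. LOC118568405, Cmpk2, Gpr171 and Oas2 completed the 10, with log2 folds of 0.80, 0.79, 0.50 and 0.74. All 10 were higher in every naringin library than in every control library. Without Control 3, limma called 1 gene, the chemokine receptor Cxcr4 (log2 fold 1.05, limma adjusted p = 0.00993), chosen for naming after its value was seen. With all 6 libraries and no sample weights its log2 fold was 0.77 and it did not pass.

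**Figure D1:**
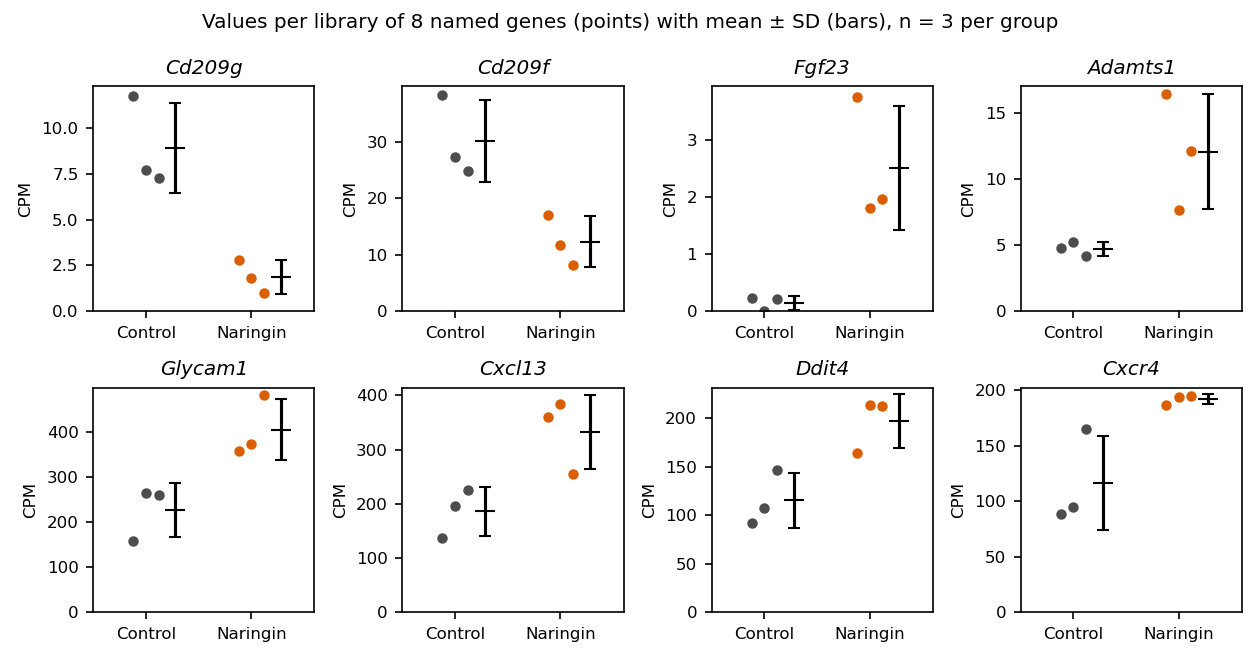
CPM (vertical axes, starting at 0) of 8 named genes in each Control and Naringin library (points), with the mean and SD over 3 libraries per group (bars). In each gene the groups do not overlap, which choosing genes from these same values favours. None passed the adjusted limma threshold with all 6 libraries and no sample weights.

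Gene lists fixed in advance were compared next, and 11 of 43 passed the camera threshold. With a correlation estimated from the data in place of the preset 0.01, 0 of the 11 passed, and 0 passed in the rotation test fry. On ranks 9 passed, but that test kept the preset correlation. The median deviations of the 3 naringin libraries lay apart from those of the 3 controls in 4 of the 11: the interferon, erythroid, glucocorticoid and regulatory T cell lists. Without sample weights no list member passed over all genes tested, so single members are given as values.

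With an estimated correlation and with fry, the glucocorticoid and erythroid lists had the smallest unadjusted p. With the preset correlation, the smallest camera p was that of the type I interferon response list, genes switched on by antiviral signalling. All 25 members were higher with naringin, with a median log2 fold of 0.61, and the list rose (camera adjusted p = 1.5e-24; adjusted p = 0.473 with an estimated correlation). Of its members, 15 had an unadjusted p under 0.05, 7 had groups that did not overlap, and 0 passed when adjusted over the list alone. The nucleotide kinase Cmpk2 averaged 17.5 ± 1.97 and 32.0 ± 10.3 CPM, the RNA-sensing enzyme Oas2 28.6 ± 6.69 and 48.1 ± 9.38 CPM, and the antiviral protein Rsad2 (viperin) 7.67 ± 1.42 and 20.4 ± 10.1 CPM in Control and Naringin. The list's median deviation per library was -0.19, -0.58 and -0.14 in the controls and 0.25, 0.60 and -0.07 with naringin. Leaving out Control 2 lowered the median log2 fold to 0.40, still past the camera threshold.

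**Figure D2:**
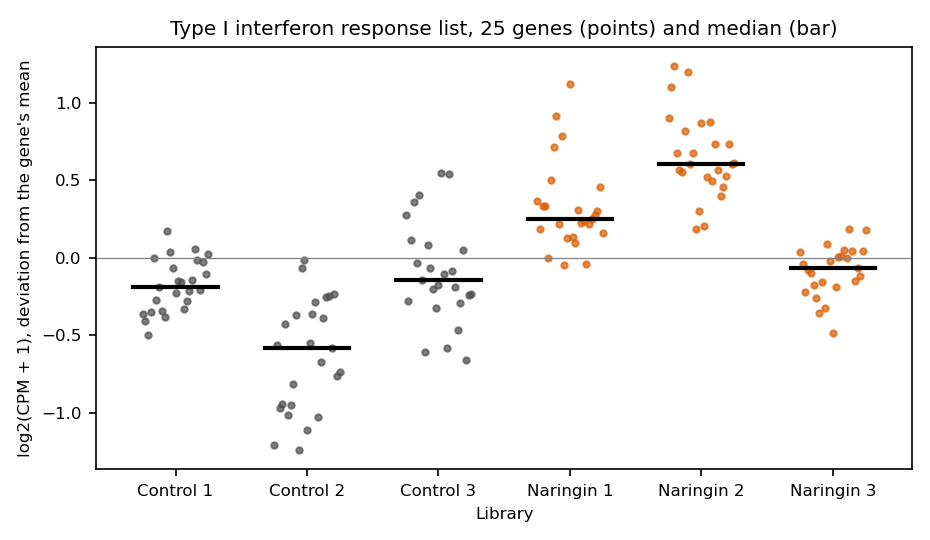
Deviation of log2(CPM + 1) from the gene's mean over 6 libraries (vertical axis) for the 25 interferon list genes (points) in each library, with the library's median (bar). The medians lie at -0.19, -0.58 and -0.14 in Control 1, 2 and 3 and at 0.25, 0.60 and -0.07 in Naringin 1, 2 and 3.

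Lymphocyte lists passed in both directions. T cell genes fell, with 19 of 21 members lower and a median log2 fold of -0.22 (camera adjusted p = 2.0e-10; adjusted p = 0.573 with an estimated correlation). The list's median deviation per library was 0.15, 0.03 and 0.16 in the controls and -0.19, -0.24 and 0.12 with naringin, so Naringin 3 lay within the control range. The T cell surface proteins Cd5 and Cd6 had log2 folds of -0.40 and -0.29, and the co-receptor Cd4, at 273 ± 18.6 and 231 ± 16.3 CPM, -0.24. Regulatory T cell genes fell as well, with 10 of 15 lower and a median of -0.15 (camera adjusted p = 0.0126; adjusted p = 0.573 with an estimated correlation). The folate receptor family member Izumo1r had a log2 fold of -0.42, the lineage factor Foxp3 -0.29 and Lrrc32, which holds latent TGF-beta at the cell surface, -0.22. B cell genes rose, with 15 of 17 higher and a median of 0.17 (camera adjusted p = 0.000481; adjusted p = 0.826 with an estimated correlation), among them Fcrl1, Ms4a1 (CD20) and Bank1 with log2 folds of 0.28, 0.31 and 0.29. Natural killer cell genes rose by a median of 0.11, with 10 of 13 higher (camera adjusted p = 0.0272; adjusted p = 0.826 with an estimated correlation), led by the receptors Klra4 and Klra8 and the granule protease Gzma at 0.66, 0.61 and 0.48. Single libraries moved several of these folds: Bank1 was at 0.094 and Klra8 at 0.39 without Control 3, Bank1 at 0.45 without Control 2, and Foxp3 at -0.18 without Control 1. Without Naringin 2, Ms4a1 was at 0.19, Cd6 at -0.19, Lrrc32 at -0.071 and Gzma at 0.30, and Lrrc32 was at -0.36 without Naringin 1. When adjusted over the list alone, 0 members passed in each of the 4 lists. The regulatory T cell call was lost without Control 1 (median -0.05) and Naringin 3 (-0.14), and its median was -0.08 without Control 2, -0.24 without Control 3 and -0.10 without Naringin 2. The B cell call was lost without Naringin 3 (0.13), with a median of 0.11 without Control 3, and the natural killer call without Control 2 (0.13), Control 3 (0.13), Naringin 1 (0.09) and Naringin 2 (0.03), with medians of 0.18 without Control 1 and 0.26 without Naringin 3.

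Genes of fat burning and of glucocorticoid action rose. In the list for PPAR alpha and fatty acid oxidation, 14 of 16 members were higher, with a median log2 fold of 0.13 (camera adjusted p = 7.5e-05, or 0.709 with an estimated correlation). The list's median deviation per library was -0.20, -0.11 and 0.02 in the controls and 0.17, 0.14 and -0.13 with naringin. Naringin 3 thus lay within the control range. Its leading members regulate fuel use: Pdk4, an inhibitor of pyruvate oxidation, at 3.24 ± 1.30 and 7.30 ± 2.23 CPM; Angptl4, a secreted inhibitor of lipoprotein lipase, at 18.4 ± 6.15 and 45.4 ± 27.6 CPM; and Cpt1a, which admits fatty acids to mitochondria, at 59.5 ± 8.57 and 88.5 ± 22.2 CPM. The median was 0.22 without Control 3, 0.08 without Naringin 1 and 0.22 without Naringin 3, each past the threshold, and 0 members passed when adjusted over the list alone. Of the glucocorticoid response list, 9 of 10 members were higher, with a median of 0.18 (camera adjusted p = 0.000857; adjusted p = 0.473 with an estimated correlation), and 0.31 without Control 2. Ddit4 passed when adjusted over the list alone, the only member to do so. Tsc22d3 (GILZ), a mediator of glucocorticoid action, averaged 196 ± 75.3 and 326 ± 35.1 CPM, and Errfi1, an inhibitor of the EGF receptor, had a log2 fold of 0.44. The log2 fold of Angptl4, 1.15 with all libraries, was 0.69 without Naringin 1, and without Control 1 that of Tsc22d3, otherwise 0.80, was 0.51 and that of Errfi1 0.28.

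The lists for red blood cells and fat cells passed in opposite directions. All 5 erythroid genes were higher, with a median log2 fold of 0.49 (camera adjusted p = 7.7e-06; adjusted p = 0.473 with an estimated correlation), and 2 passed when adjusted over the list alone. The haemoglobin genes Hba-a2, Hbb-bs and Hba-a1 had log2 folds of 0.52, 0.56 and 0.49, with Hba-a1 at 0.30 without Control 2. Hbb-bs averaged 19.2 ± 5.04 and 28.2 ± 3.11 CPM in Control and Naringin. Adipocyte genes fell, with 12 of 14 lower and a median of -0.33 (camera adjusted p = 8.9e-05; adjusted p = 0.626 with an estimated correlation), and 0 passed when adjusted over the list alone. The lipogenic factor Thrsp, the fat cell protease Cfd (adipsin) and the carbonic anhydrase Car3 had log2 folds of -0.54, -0.94 and -0.85. Control 1 and Naringin 3 carried much of this: Cfd was at -0.34 and Car3 at -0.37 without Control 1, and at -0.40 and -0.38 without Naringin 3, while Car3 was at -1.34 without Control 3. The adipocyte call was lost without Control 1 (-0.13) and without Naringin 3 (-0.07), and its median was -0.58 without Control 3.

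Dendritic cell genes fell, with 12 of 15 lower and a median log2 fold of -0.15 (camera adjusted p = 0.00126; adjusted p = 0.473 with an estimated correlation). Cd209a, the chemokine Ccl17 and the actin-bundling protein Fscn1 of mature dendritic cells had log2 folds of -0.55, -0.56 and -0.24. Without Control 3, Ccl17 was at -0.34 and Fscn1 at -0.12, and Fscn1 was at -0.15 without Control 1 and -0.45 without Control 2. The call was lost without Control 3 (-0.10), and without Naringin 3 the median was 0.0015. Cytosolic ribosomal protein genes fell slightly, with 33 of 34 lower and a median of -0.08 (camera adjusted p = 0.000953; adjusted p = 0.868 with an estimated correlation). Rpl12 and Rps24 had log2 folds of -0.15 and -0.14, and of 0.010 and -0.0061 without Control 3. This list rested on Control 3, in which its genes took 6.62% of the reads against 4.57% to 5.33% in the other libraries: without Control 3 the median was 0.09 in the other direction (camera adjusted p = 0.00181), and without Naringin 1 it was -0.01 and not past the threshold. It was -0.16 without Control 1, -0.18 without Control 2 and -0.13 without Naringin 3. When adjusted over the list alone, 0 members of either list passed.

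**Figure D3:**
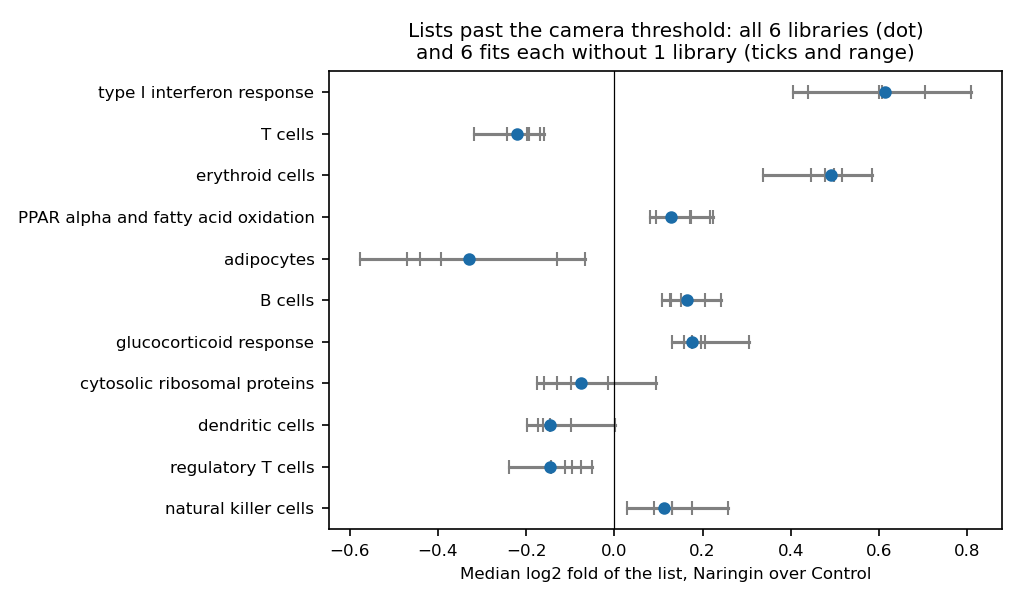
Median log2 fold, Naringin over Control (horizontal axis), of the 11 lists past the camera threshold with all 6 libraries (dots) and in 6 fits that each leave out 1 library (ticks, with their range as a line). The interferon list keeps medians from 0.40 to 0.81, while the ribosomal protein list runs from -0.18 to 0.09.

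The remaining 32 lists did not pass. Neutrophil genes had a median log2 fold of 0.37 with 10 of 13 higher (camera adjusted p = 0.138), led by Hdc at 0.84 and Cxcr2 at 0.48. With all 6 libraries that list passed under upper-quartile scaling (adjusted p = 0.0380), quantile normalization (0.0419), the length correction (0.0235), the macrophage covariate (0.00107) and sample weights (9.2e-07). Follicular and reticular stroma had a median of 0.09 (adjusted p = 0.151) and held Cxcl13 and Bst1 at 0.84 and 0.47, and blood and high endothelium had 0.06 (adjusted p = 0.151), with Glycam1 and Madcam1, the venule ligands for lymphocyte homing, at 0.85 and 0.37. Proliferation genes had a median of 0.09 (adjusted p = 0.151), with Aurkb at -0.34 and Pcna at 0.16, and collagens and matrix had 0.22 (adjusted p = 0.275), with Fn1 at 0.51 and Col6a3 at 0.51. The collagen list passed with the adipocyte covariate (median 0.54, adjusted p = 0.000128), as did proliferation (0.12, adjusted p = 0.0350), and with the macrophage covariate (0.18, adjusted p = 0.0456). With sample weights the collagen (0.31), proliferation (0.13), stroma (0.30), macrophage (0.27), mast cell (1.43) and lymphatic (0.61) lists passed as well. The antioxidant NRF2 list and the NF-kB list, pathways often tested for flavonoids, had medians of 0.03 and 0.04 (adjusted p = 0.559 and 0.664), with Gsr and Pgd at 0.40 and 0.17 and Il1b and Nfkbia at 0.67 and 0.12. Macrophage genes had a median of 0.01 while camera's direction was down (adjusted p = 0.903), with Ccr2 at 0.30 and Cd68 at -0.20. Skeletal muscle genes had -0.18 (adjusted p = 0.138), with Eno3 and Mylpf at -0.19 and -0.18. Mast cell and lymphatic endothelial genes had medians of 0.07 each (adjusted p = 0.711 and 0.878). The other 21 lists had adjusted p from 0.151 to 0.996.

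Several of these lists hung on single libraries, and their medians moved both ways when 1 was left out. Without Naringin 3, camera called as higher the neutrophil (median 0.90), proliferation (0.13), NRF2 (0.13), macrophage (0.43), stroma (0.28), endothelium (0.15), collagen (0.64), mast cell (0.91) and lymphatic (0.57) lists. Without Control 3 it called the neutrophil (0.76), proliferation (0.14), NRF2 (0.12), macrophage (0.26), stroma (0.15) and collagen (0.38) lists. Without Naringin 1, Hdc was at 0.46, Cxcr2 at 0.046, Il1b at 0.29, Gsr at 0.22 and Madcam1 at 0.20. In the same fit Ccr2 was at 0.0055, Fn1 at -0.0041 and Col6a3 at -0.061. Without Naringin 3, Cxcr2 was at 0.95, Madcam1 at 0.66 and Ccr2 at 0.57. Ccr2 was at 0.56 without Control 1, and Pgd at 0.27 without Control 3. Without Naringin 1 camera called as lower the macrophage (-0.23), collagen (-0.23) and lymphatic (-0.47) lists. Without Control 2 the medians of the neutrophil (0.065), proliferation (0.035), collagen (0.022) and NRF2 (0.0024) lists were lower than with all 6, and without Naringin 1 those of the neutrophil (-0.086), proliferation (0.054), stroma (-0.053), endothelium (-0.090) and NRF2 (-0.064) lists. Without Control 1 the neutrophil (0.15), stroma (-0.031), endothelium (-0.083) and NF-kB (0.013) medians were lower. The NF-kB median was 0.087 without Naringin 3. The muscle median was -0.12 without Control 1 and -0.059 without Naringin 1, where Mylpf was at -0.057. Bst1 was at 0.27 and Madcam1 at 0.18 without Control 1. The endothelial list also passed without Control 2 (0.19) and Naringin 2 (0.11), and the muscle list without Naringin 2 (-0.23). The number of lists past the threshold was 20 without Control 3 and 18 without Naringin 3.

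Control 3 stood apart from the other libraries. On the component with most of the variance (47.2%), it lay at 42.9, against -20.2 to 10.2 for the other 5. Genes with a short total exon length were high in it and those with a long one low: across 13956 genes, which are not independent replicates, its deviations had a Spearman correlation with exon length of -0.52, against -0.04 to 0.40 in the other libraries. Mitochondrially encoded genes took 1.35% of its reads and 1.82% to 1.94% of those of the others.

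**Figure D4:**
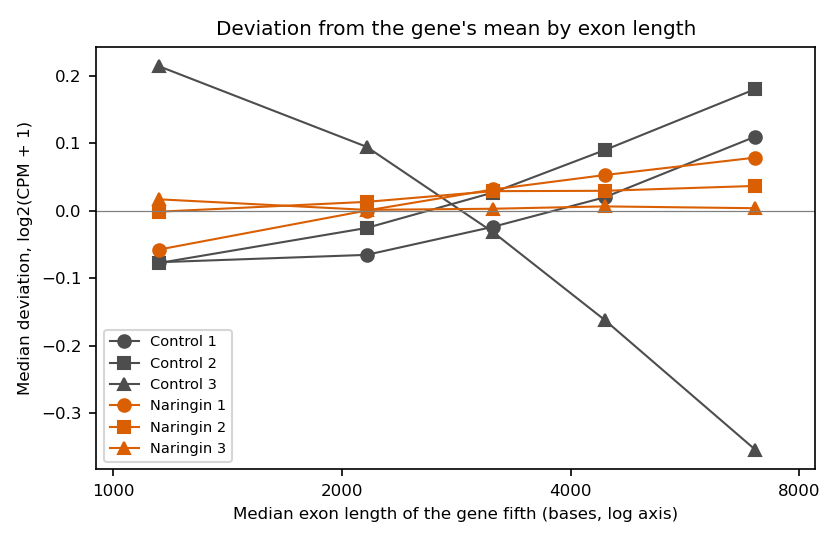
Median deviation of log2(CPM + 1) from the gene's mean (vertical axis) in 5 groups of genes by total exon length in bases (horizontal log axis), 1 line per library. Control 3 runs from 0.21 in the group with the shortest total exon length to -0.35 in that with the longest, and the other libraries lie between -0.08 and 0.18.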

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

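The gene-length correction, its use without Control 3 and the macrophage covariate were chosen after the data were seen. Apart from the values given here and the counts at the end, results kept their direction and side of the threshold. The count of 0 genes became 1367 (560 higher, 807 lower) with sample weights, 3 (1 higher, 2 lower) with DESeq2 and 1 higher gene with length-corrected values and no Control 3, and ran from 0 to 1 higher gene when a library was left out. With all 6 libraries and no weights, limma called 0 genes at an adjusted p under 0.1 too, with 213 at an unadjusted p under 0.05. The count of 11 lists became 0 with an estimated correlation and 0 with fry, whose medians are those already given: interferon 0.61, T cells -0.22, erythroid 0.49, PPAR alpha 0.13, adipocytes -0.33, B cells 0.17, glucocorticoid 0.18, ribosomal -0.08, dendritic -0.15, regulatory T -0.15 and natural killer 0.11. It was 19 with sample weights and 10 to 20 when a library was left out. Without a filter on low values the regulatory T, natural killer (0.11) and ribosomal (-0.0765) calls were lost, on ranks the regulatory T (-0.15) and natural killer calls, and with a minimum mean of 5 CPM the natural killer call (0.055); that minimum left too few erythroid and skeletal muscle genes to test. With the adipocyte covariate the adipocyte median was 0.025, by construction, with Adipoq at 0.034, and the B cell (0.13) and regulatory T (-0.058) calls were lost. With length-corrected values and no Control 3 the B cell (0.079), natural killer (0.085) and dendritic (-0.085) calls were lost and the ribosomal median was 0.044. Sample weights gave 0.076 for the ribosomal list, -0.025 for dendritic cells, 0.020 for Rpl12 and -0.073 for Ccr2. Medians near 0 changed sign: macrophages under median-of-ratios (-0.0085), upper-quartile (-0.033) and quantile (-0.011) scaling and the macrophage covariate (-0.019), NF-kB under upper-quartile (-0.0076) and quantile (-0.00019) scaling and the length correction (-0.00033), NRF2 under upper-quartile scaling (-0.0094), and mast cells at a minimum of 5 CPM (-0.022) and with the macrophage covariate (-0.022). Quantile scaling gave -0.0038 for the ribosomal list, ending its call, and 0.00063 for Rps24. Leave-one-out medians ran from 0.11 to 0.24 for B cells, -0.24 to -0.051 for regulatory T cells, 0.030 to 0.26 for natural killer cells, -0.20 to 0.0015 for dendritic cells, -0.58 to -0.066 for adipocytes, -0.18 to 0.094 for ribosomal genes, -0.23 to 0.43 for macrophages, -0.086 to 0.90 for neutrophils, -0.053 to 0.28 for stroma, -0.090 to 0.19 for endothelium, -0.23 to 0.64 for collagens, -0.064 to 0.13 for NRF2, -0.40 to 0.91 for mast cells and -0.47 to 0.57 for lymphatic endothelium. Leave-one-out log2 folds ran from -0.43 to 0.034 for Cd68, -0.0041 to 0.93 for Fn1, -0.061 to 0.90 for Col6a3, -0.24 to 0.010 for Rpl12, -0.30 to 0.034 for Cd3e and -0.34 to 0.64 for Cd209b. The cause of these changes was not tested. Same-numbered samples did not deviate together across genes (r = -0.26, -0.02 and -0.27). Deviations from a group's own mean sum to 0, so these values cannot exclude a pairing. With a replicate block 0 genes and the same 11 lists passed. For the 75 named genes, 1572 values under an alternative kept their direction and their side of the threshold, 44 newly passed and 13 changed sign. Nearly all that newly passed did so with the sample weights, whose estimate did not converge. The rest were Cd209g, Cd209f and Fgf23 with DESeq2, and Cxcr4 without Control 3, with and without the length correction. For the 11 other lists described, 38 values newly passed in the same direction, mostly with sample weights or with a library left out, and 27 changed sign. Among those that changed sign, the macrophage, collagen and lymphatic lists passed without Naringin 1. Isotype shares and their alternatives were not run, because nearly all heavy chain constant genes were listed at 0. A read was worth at most 0.0765 CPM, so depth limits only genes of a few reads, such as Fgf23 in Control.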

Other observations

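The tests in this part were chosen after the results were seen, except the comparison of lists across other splits of the libraries. A set of non-lymphoid lists varied together across libraries of both groups. Mast cell genes had median deviations of -0.92, -0.27 and 0.70 in Control 1, 2 and 3 and 0.92, 0.83 and -1.27 in Naringin 1, 2 and 3. Lymphatic endothelial genes followed with -0.71, 0.26 and 0.32, then 0.90, 0.15 and -0.99, macrophage genes with -0.25, -0.23 and 0.46, then 0.68, 0.16 and -0.72, and neutrophil genes with -0.89, -0.74 and 1.32, then 1.11, 0.34 and -0.86. Fcer1a, a subunit of the IgE receptor of mast cells, ranged from 0.70 CPM in Naringin 3 to 7.28 CPM in Naringin 2. The mast cell growth factor receptor Kit did not follow the list, with 15.6 CPM in Control 3, 18.8 CPM in Naringin 3 and 27.0 CPM in Naringin 1. Lyve1, the hyaluronan receptor of lymphatic vessels, ranged from 42.9 CPM in Control 1 to 148 CPM in Naringin 1, and the chemokine scavenger Ackr2 from 2.91 to 14.1 CPM in the same libraries.

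The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 0 genes, higher or lower, and another called 2; at an unadjusted p under 0.05 the real split had 213 genes and the split of Control 1, Control 2 and Naringin 3 from the rest had 2503, which points to a structure of the samples other than the treatment. The real split passed 11 lists and another passed 18, and 9 of the 10 splits passed at least as many. The absolute medians of the interferon (0.61) and erythroid (0.49) lists were the largest of the 10, in 1 split each, with 0.59 and 0.41 as the highest others. As large a median came in 2 splits for B cells (0.17, highest other 0.24), T cells (0.22, 0.25), regulatory T cells (0.15, 0.15) and the glucocorticoid list (0.18, 0.23), in 3 for dendritic cells (0.15, 0.17), in 4 for natural killer cells (0.11, 0.30), in 5 for the PPAR alpha list (0.13, 0.26), in 6 for adipocytes (0.33, 0.53) and in 8 for ribosomal proteins (0.08, 0.28). The split of Control 1, Control 2 and Naringin 3 from the rest gave the highest other median of the interferon, PPAR alpha and glucocorticoid lists. Those of the remaining lists came from other splits.

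The higher interferon list had a lowest leave-one-out median of 0.40, without Control 2. The size of that median argues against a single library as its source. It was past the camera threshold too, but other splits of the libraries passed as many lists, so passing adds little. The length trend of Control 3 as the whole cause is argued against by a median of 0.57 after the length correction. A larger share of macrophages would raise macrophage genes at least as much, but their list had a median of 0.01 and an upper quartile of 0.14. That quartile is over genes, not samples. The macrophage median was -0.23 without Naringin 1 and 0.43 without Naringin 3, where the interferon median was 0.61 and 0.81. Several explanations stay open. Chance was examined by the splits, which are too few to decide it. The split of Control 1, Control 2 and Naringin 3 from the rest gave 0.59, nearly the value of the real split. That is the split with 2503 genes at an unadjusted limma p under 0.05. A GC trend, a share of other cell types, a different exposure of single nodes and an effect of the treatment were not tested for this list. Each is a hypothesis that may or may not hold. The call also rests on the preset correlation, with an adjusted p of 0.473 under an estimated one.

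The lower Cd209g and Cd209f could reflect fewer macrophages in the naringin nodes. A loss of every kind of macrophage is argued against by the macrophage list, whose median log2 fold was 0.01 and upper quartile 0.14, against -1.26 for Cd209f. The quartile is over genes, and the list's leave-one-out medians ran from -0.23 to 0.43. Reads moved to another member of the family in counting cannot be told apart from a true difference: the 7 genes summed to 683 ± 206 CPM in Control and 725 ± 397 CPM with naringin (log2 ratio 0.087), and the spread of Cd209b, at 267 to 1043 CPM, exceeds all that Cd209g and Cd209f lost. A loss of a subset of macrophages or dendritic cells that carries these lectins, with or without the treatment as its cause, stays open and untested.

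Control 3 may differ from the rest through its RNA or library rather than its node. Its deviations followed exon length (Spearman correlation across genes -0.52) and, at a given length, GC content (partial correlation 0.38), both as a length- or GC-dependent loss of reads would give. Naringin 2 had a partial correlation with GC of -0.34. Deviations were taken from the mean of all libraries, so a trend in Control 3 pushes the others the opposite way. Whether Naringin 2 has a GC trend of its own is therefore not decided. Another cell content is not decided: after the length correction its neutrophil median lay 0.092 above that of Naringin 1, within the spread of the members (interquartile range 1.26). The design names no difference within the Control group, and no other biological explanation was tested.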
